A study of Homo sapiens with 16 samples.

How the data were processed

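RNA from ALDH-high and ALDH-low cells of the lines PC9 and PC9M2 was measured on 16 one-colour Agilent expression arrays, 4 arrays for each of the 4 combinations of line and ALDH population. Per the labels' protocols, the cells were grown in RPMI-1640 with serum, RNA was purified with the RNeasy kit, and it was labelled with Cy3 by the Low Input Quick Amp method. The labels call the 4 arrays of a group biological replicates and do not say how PC9M2 was made or how the ALDH populations were separated.

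The scanner files hold, per the file headers, Feature Extraction 11.0.1.1 output with the intensity of each spot as a background-subtracted processed signal on a linear scale. They also hold spot flags (well above background, outlier, saturated) as 0 or 1 values, per the file headers. The authors' processed values for 41363 probes were deposited as a linear ratio. No header or label states their scale. From the values, each is a probe's processed signal divided by about the 75th percentile of 1 array. Column medians lay between 0.221 and 0.251. The header of the scanner files names genome build 37, and no coordinates were used.

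Each array had 60901 non-control spots for 58201 probes, of which 57901 were present once and 300 were present 10 times and averaged. The files carry no gene symbols, so 31104 probes were named through their RefSeq accession against the GRCh38.p14 gene table, used for names only, which gave 22439 genes. The other 27097 probes had no name and stayed out of the gene tests. Between 55.4% and 61.4% of spots on an array were well above background, 34 to 123 spots per array were marked as outliers, 0 were saturated, and the 75th percentile of the signal lay between 572 and 988. The number of arrays limits the precision.

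Signals were log2 transformed and each array's 75th percentile was subtracted. A probe was kept if it was well above background on at least 3 of the 4 arrays of any group, and the brightest kept probe stood for its gene, which left 17086 genes. In all 4 groups, replicates 1 and 3 agreed within spot noise, and so did replicates 2 and 4. For these 8 pairs of arrays the difference between arrays was 0.710 to 1.03 times the difference between spots of 1 probe on 1 array, and for the other 16 pairs within groups it was 6.39 to 12.3 times. These ratios rest on 287 repeated probes above background on every array. Over all 27864 probes above background on every array, the robust SD between arrays was 0.0762 to 0.116 against 0.403 to 0.537 on the log2 scale. The labels do not state that paired arrays hold 1 RNA, which is inferred from this agreement. The paired arrays were therefore averaged to 8 RNA samples, n = 2 per group, with 4 residual degrees of freedom and 2.21 prior degrees of freedom. This departs from the planned 16-array fit with 12 residual degrees of freedom, which is given as an alternative. All log2 fold changes, SE and SD refer to these RNA samples unless another fit is named.

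Group means were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with empirical Bayes moderation and Benjamini-Hochberg adjustment over all 17086 genes, and a gene was called at an adjusted p below 0.05. The comparisons were PC9M2 against PC9 within ALDH-high and within ALDH-low, ALDH-high against ALDH-low within each line, and the difference of the line effects between ALDH-high and ALDH-low. Every p-value measures only the spread between these RNA samples, which may be technical. A gene whose probe was well above background on all 4 arrays of a group, while no probe of it was on any array of the other group, is given as a lower bound, "at least N-fold". The bound sets the mean of the bright group against the lowest signal that counted as well above background on each array of the dim group, or the gene's own signal there where that was higher. The same bound was taken for the second probe of ALDH1A1, after the data were seen.

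Replicate numbers were checked for pairing. All 24 correlations of same-numbered arrays of different groups, taken on deviations from the group means, lay between 0.574 and 0.892. Correlations with the other replicate pair were negative and of similar size, since the deviations of the pairs in a group mirror each other. The 24 values are therefore not independent, and they match replicate pairs across groups, not single numbers. All 24 were highest with their own number, but same-numbered arrays also shared a slide, so number and slide cannot be told apart. The pairing of replicate pairs across groups comes from these values and not from the labels. The fit with the replicate pair as a block had 3 residual degrees of freedom and took out only the part of the pair difference that the groups shared.

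The 40 gene lists held 702 members, of which 613 were measured, and each comparison was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists. Lists with fewer than 3 measured members were not to be tested, and none fell below this. The lists were aldehyde dehydrogenases, retinoic acid response, Musashi proteins and reported target mRNAs, pluripotency factors, stem cell surface and transporter markers, epithelial and mesenchymal genes, ERBB receptors and ligands, other receptor tyrosine kinases and ligands, ERK feedback, immediate early genes, G1/S and G2/M genes, cyclin-dependent kinase inhibitors and senescence, p53 targets, the BCL2 family, ABC transporters and NRF2 targets. The others were alveolar, neuroendocrine and squamous genes, interferon-stimulated genes, MHC class I and antigen presentation, NF-kB cytokines, Notch, Wnt, TGF-beta and YAP/TAZ genes, hypoxia, glycolysis, oxidative phosphorylation, the unfolded protein and amino acid stress response, cholesterol synthesis, fatty acid synthesis, ribosomal proteins and replication-dependent histones. Markers of fibroblasts, endothelium, leukocytes and erythroid cells were included as other cell types.

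The genes named in the text followed a rule. It took MSI2, MSI1, ALDH1A1, ALDH1A3, ALDH3A1, EGFR, MET, AXL and NANOG where measured, the 10 largest changes per direction in the first comparison and 8 in the second among called protein-coding genes above background on every array of the groups compared, 4 per direction by lower bound, and up to 4 called members of each list, or 2 members where none was called. A few genes that the rule takes are not reported. The comparisons, tests, filter, scaling, lists, naming rule and most alternatives were fixed before the data were examined.

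The alternatives fixed in this way were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' processed values, no filter and a filter on all 16 arrays, the mean of a gene's probes, a trended robust prior, only the groups compared, the replicate block, array weights, slide as a fixed block on the 16 arrays with the replicate pair as a random block, an estimated correlation in camera and leaving out each array. Normexp used the median spot signal because the files hold no mean signal. The replicate pairs were found from the data, so the replicate block and the random block on the pair were not fixed in this form. The 16-array fit without a block had been planned as the main fit and became an alternative. Those added after the data were seen were the 16-array fit with a replicate block, leaving out each RNA sample, the arrays of 1 slide, the series columns matched to arrays, and all probes in place of 1 per named gene. With 2 RNA samples per group, other splits of the samples were not counted.

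The fit was tested on 10 simulated data sets of 17086 genes. For PC9M2 against PC9 within ALDH-high it called 0.448%, 47.2% and 71.7% of genes changed by 1, 2 and 3 on the log2 scale, and with the replicate block 61.9%, 94.9% and 98.5%. False calls numbered 0 and, with the block, 10.7 per data set. For ALDH-high against ALDH-low within PC9 the shares were 0.896%, 47.0% and 71.8%, and 64.6%, 95.5% and 98.8% with the block, with 10.8 false calls per data set with the block. A simulated list of 16 genes shifted by 1 was called in 10 of 10 data sets with the preset correlation. With an estimated correlation it was called in 0 of 10 without the block, and with the block in 5 of 10 for the lines and 10 of 10 for ALDH in PC9. The simulated data had 1 pair effect shared by all groups and noise that was independent between genes. In the data the pair effect was only partly shared by the lines, and genes of a list were correlated (0.900 for G1/S genes). The shares and false calls therefore hold for the simulated setting only and do not bear out the preset correlation.

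The authors' processed values were compared with the scanner files and were not used for the main values. Of their 16 columns, 4 held the values of the array they are labelled with and 12 held those of another array, with an SD of at most 3.35e-07 against at least 0.472 for the next best array. The arrays lay on 2 slides of 8 arrays, with replicates 1 and 2 on the first slide and replicates 3 and 4 on the second. On both slides ALDH-high PC9M2 lay in row 1, ALDH-low PC9M2 in row 2, ALDH-high PC9 in row 3 and ALDH-low PC9 in row 4. Group and row therefore cannot be told apart. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.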

Results

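Gene expression was measured in ALDH-high and ALDH-low cells of PC9, a lung adenocarcinoma line with a mutant EGFR, and of PC9M2, which the labels set against PC9 without saying how it was made. Aldehyde dehydrogenase (ALDH) activity is commonly used to enrich stem-like tumour cells. Each of the 4 groups had 4 arrays. Replicates 1 and 3 of every group agreed within spot noise, as did replicates 2 and 4, so each such pair was averaged to 1 RNA sample, which left n = 2 per group. The number of arrays limits the precision. On the first principal component, which held 58.3% of the variance, the arrays separated by line. On the second component, which held 26.6%, they separated by replicate pair. The third, with 5.15%, separated the replicate pairs in opposite directions in the 2 lines, so the pair difference was only partly shared by the lines. The fourth, with 2.45%, followed the ALDH population.

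**Figure D1:**
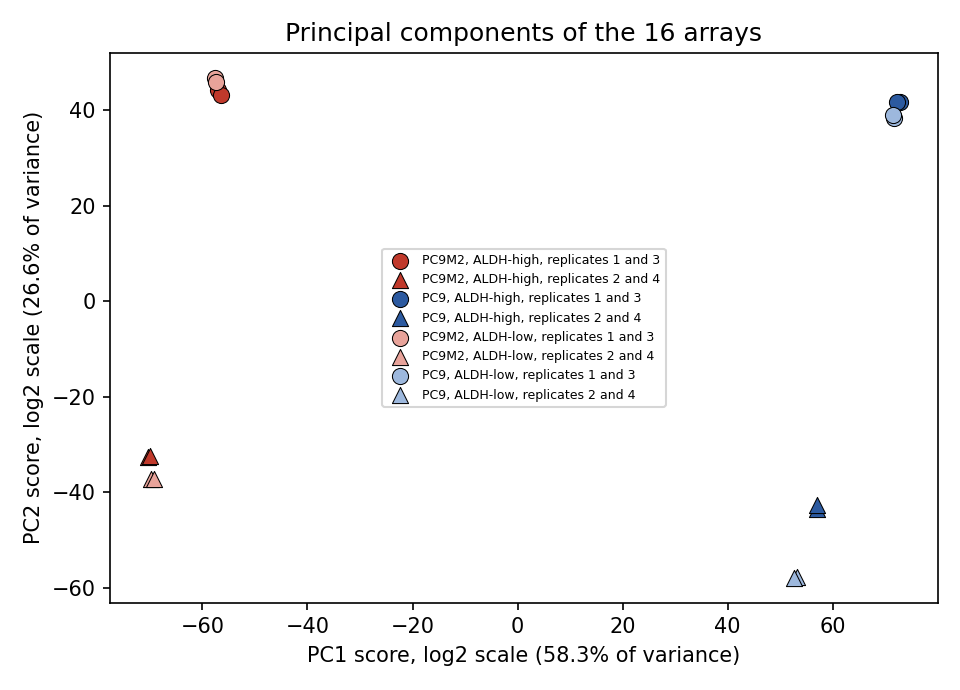
Principal components of 16 arrays over 27828 probes, with PC1 on the horizontal axis and PC2 on the vertical axis, in which each point is 1 array coloured by group. PC1 (58.3% of the variance) separates PC9M2 from PC9 and PC2 (26.6%) separates replicates 1 and 3 from replicates 2 and 4.

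The first comparison asked how PC9M2 differed from PC9 among ALDH-high cells, the comparison named in the series design, whose title concerns MUSASHI-2 and osimertinib resistance. MSI2 (NM_138962), which encodes the RNA-binding protein MUSASHI-2, was higher in PC9M2 by 2.99 ± 0.65 on the log2 scale (SE, n = 2 per group, limma adjusted p = 0.0332). MET (NM_000245), a receptor tyrosine kinase that can bypass EGFR inhibition, fell by 2.18 ± 0.18 (adjusted p = 0.00131), and AXL (NM_021913), another such kinase, fell by 2.60 ± 0.32 (adjusted p = 0.0056). The lists of mesenchymal, interferon response and antigen presentation genes were lower in PC9M2, with medians of −1.46, −1.07 and −1.01. They had adjusted p = 0.287, 0.287 and 0.371 with an estimated correlation. The list of oxidative phosphorylation subunits was higher, with a median of 0.36 and 3 of 31 members called (adjusted p = 0.768 with an estimated correlation). All genes had a median of 0.12 under this scaling, against which list medians are to be read.

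Of the other genes followed in every comparison, none passed the test here with the probe that stood for it. EGFR (NM_005228), the drug target, differed by −0.02 ± 0.59 (adjusted p = 0.984), and by 0.09 when arrays were centred on their median. MSI1 differed by −0.27 ± 0.26 (adjusted p = 0.559) and ALDH1A3 by 0.29 ± 0.32 (adjusted p = 0.598). ALDH3A1 differed by −2.46 ± 0.66 (adjusted p = 0.0635, and 0.00314 with the replicate pair as a block). ALDH1A1 differed by −1.30 ± 0.64 (adjusted p = 0.246, and 0.034 with the block). The ALDH1A1 probes disagreed, since a second one was above background on all 4 arrays of PC9 and on none of PC9M2, at least 119-fold lower in PC9M2 (adjusted p = 0.00714 over all probes). MSI2 also had a dimmer probe (NM_170721), which differed by 0.32 ± 0.38 (adjusted p = 0.653 over all probes). MSI2 was not called with any 1 RNA sample left out, though its difference stayed positive. It was 2.50 (adjusted p = 0.154) without PC9M2 replicates 1 and 3 and 3.48 (adjusted p = 0.0834) without PC9M2 replicates 2 and 4. The values were 3.36 (adjusted p = 0.101) without PC9 replicates 1 and 3 and 2.62 (adjusted p = 0.143) without PC9 replicates 2 and 4. Within the replicate pairs the MSI2 difference was 3.11 and 2.87, with adjusted p = 0.000382 with the block. NANOG was above background on 3 arrays and was not tested.

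**Figure D2:**
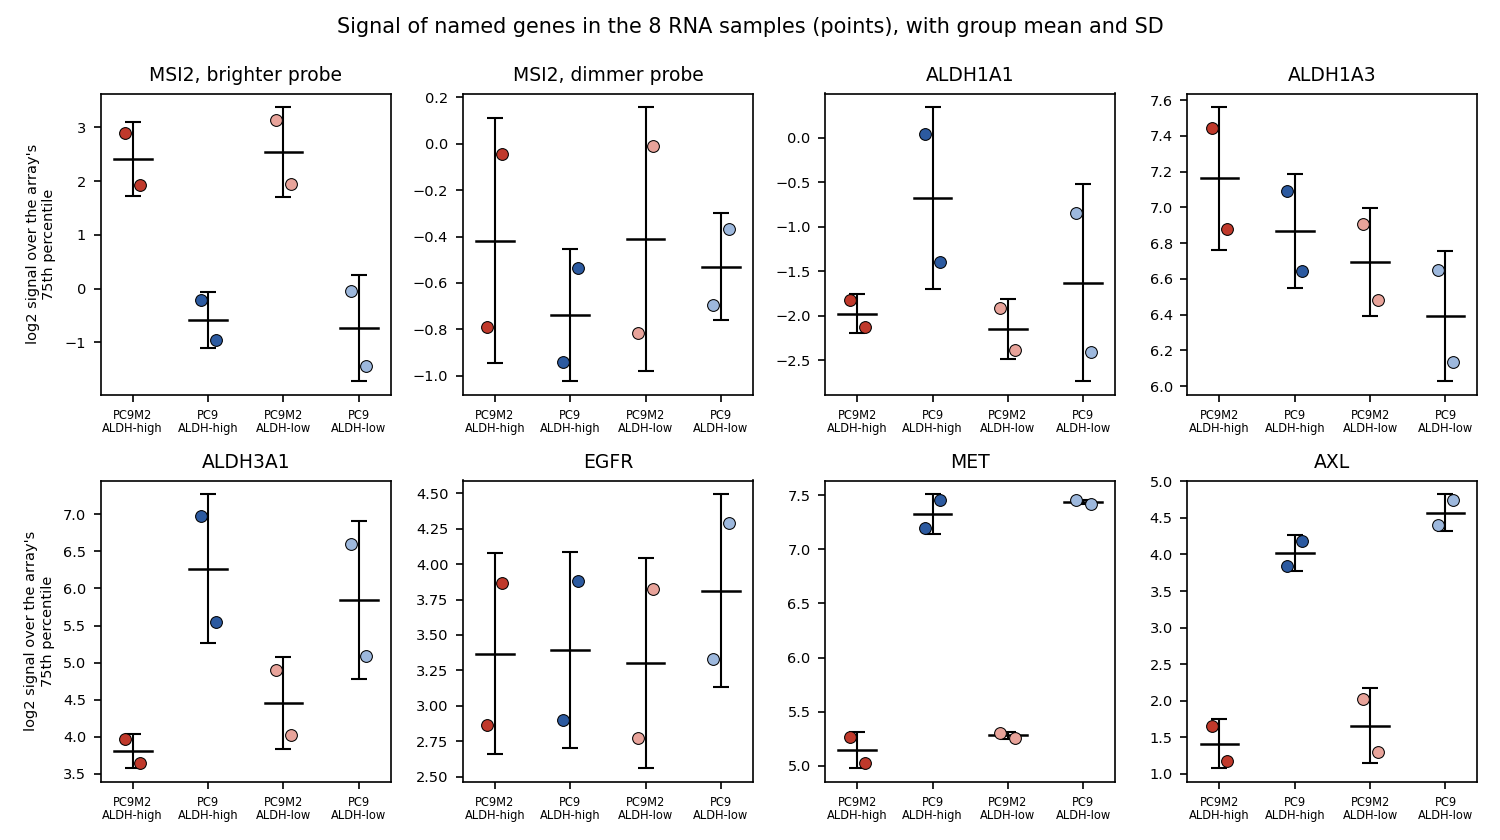
Log2 signal over the array's 75th percentile (vertical axis) in the 4 groups (horizontal axis) for MSI2 (both probes), ALDH1A1, ALDH1A3, ALDH3A1, EGFR, MET and AXL, in which points are RNA samples and bars are the group mean with SD (n = 2). ALDH1A1 is shown by the probe that stood for the gene, without its second probe. The brighter MSI2 probe averaged 2.41 in ALDH-high PC9M2 and −0.58 in ALDH-high PC9.

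Among genes above background on every array of the groups compared, the largest rises in PC9M2 were S100A9, a calcium-binding protein of inflammation (7.96 ± 0.17), the glutamate transporter SLC1A3 (7.61 ± 0.27) and DHRS2 (6.67 ± 0.29). OLFML3 (6.11 ± 0.25), the protease inhibitor PI3 (5.54 ± 0.80), WNT6 (5.13 ± 0.89), DIO3 (5.11 ± 0.68), the neuronal splicing factor NOVA1 (5.03 ± 0.67), the embryonic globin HBE1 (4.91 ± 0.87) and ONECUT2 (4.79 ± 0.18) followed. The largest falls were in the carboxylesterase CES1 (−8.13 ± 0.19), the nuclear receptor NR0B1 (−8.10 ± 0.81), BAIAP2L2 (−7.20 ± 0.97), CDK14 (−6.57 ± 0.20) and DOCK10 (−6.53 ± 0.45). CDH2, the N-cadherin of mesenchymal cells, fell by 6.18 ± 0.29, and CAVIN3 (−6.14 ± 0.35), ID4 (−6.05 ± 0.31), SLC16A4 (−5.99 ± 0.72) and the matrix protein SPARC (−5.92 ± 0.37) fell as well. Adjusted p for these 20 genes lay between 1.74e-05 for S100A9 and 0.0182 for HBE1. Of the genes seen in ALDH-high PC9M2 and not above background in ALDH-high PC9, SLC1A6 was at least 263-fold higher (adjusted p = 2.6e-05), and MAGEA9 at least 198-fold (adjusted p = 1.5e-05). TCF4 was at least 174-fold higher (adjusted p = 8.92e-05) and PASD1 at least 168-fold (adjusted p = 1.75e-05). In the other direction, the protease HTRA1 was at least 329-fold lower (adjusted p = 1.79e-05) and the growth factor PTN at least 237-fold (adjusted p = 1.74e-05). SELENBP1 was at least 138-fold lower (adjusted p = 0.000796) and PTPRR at least 121-fold (adjusted p = 0.000104).

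Mesenchymal genes were the list that fell furthest. Of 18 measured members 10 fell and 0 rose (10 and 0 adjusted over the list alone), among them CDH2 and SPARC. The transcription factor TWIST2 was at least 33.4-fold lower. The list had camera adjusted p = 5.88e-09, and adjusted p = 0.287 with an estimated correlation. Beside them, the 4 measured fibroblast markers had a median of −1.17 (adjusted p = 0.0567), of which COL1A2 was at least 2.86-fold lower. TGF-beta target genes had a median of −0.73, and 5 of 18 fell and 1 rose (9 and 2 adjusted over the list alone). CCN2, above background on 2 of 4 PC9M2 arrays, changed by −5.14 ± 0.81 and TIMP3 by 1.86 ± 0.27 (list adjusted p = 0.0128, and adjusted p = 0.333 with an estimated correlation). Interferon-stimulated genes fell in 9 of 28 cases and rose in 0 (14 and 0 adjusted over the list alone). XAF1 was at least 26.2-fold lower, HERC5 changed by −4.15 ± 0.54, IFI44 by −4.12 ± 0.48 and MX2 by −3.68 ± 0.56 (list adjusted p = 4.9e-07, and adjusted p = 0.287 with an estimated correlation). In the MHC class I and antigen presentation list 7 of 15 fell and 0 rose (11 and 0 adjusted over the list alone). They included the immunoproteasome subunit PSMB9 (−2.60 ± 0.42), the peptide transporter TAP1 (−1.64 ± 0.23), HLA-B (−1.61 ± 0.23) and HLA-F (−1.43 ± 0.22). The list had adjusted p = 1.51e-06, and adjusted p = 0.371 with an estimated correlation.

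ERBB receptors and ligands had a median of −0.60, and 4 of 12 fell and 0 rose (6 and 1 adjusted over the list alone). The members that fell were all ligands, EPGN at least 3.69-fold, NRG4 (−3.39 ± 0.40, above background on 3 of 4 PC9M2 arrays), AREG (−3.04 ± 0.75) and EGF (−2.41 ± 0.59). The list had adjusted p = 0.0165, and adjusted p = 0.333 with an estimated correlation. Cyclin-dependent kinase inhibitors and senescence genes had a median of −1.29 with 4 of 11 lower and 0 higher (4 and 1 adjusted over the list alone), among them IGFBP7 (−9.70 ± 0.17, above background on 2 of 4 PC9M2 arrays), CDKN1A (−2.33 ± 0.57) and CDKN2C (−1.29 ± 0.31). That list had adjusted p = 0.0169, and adjusted p = 0.379 with an estimated correlation. NRF2 target genes, part of the oxidant defence, had a median of −0.42, and 2 of 21 fell and 0 rose (2 and 0 adjusted over the list alone), SLC7A11 by −1.75 ± 0.28 and ABCC2 by −1.71 ± 0.26. The NRF2 list had adjusted p = 0.0168, and adjusted p = 0.876 with an estimated correlation. Without PC9 replicates 1 and 3 its call ended at a median of −0.18, against −0.83 without PC9 replicates 2 and 4. Oxidative phosphorylation subunits rose in 3 of 31 cases and fell in 0 (3 and 0 adjusted over the list alone), with ATP5PB at 1.36 ± 0.25, ATP5F1A at 1.25 ± 0.16 and COX5B at 0.70 ± 0.16. The adjusted p was 0.00745, and adjusted p = 0.768 with an estimated correlation. The median was 0.16 with quantile normalization, where the call ended. G2/M mitotic genes had a median of 0.52 with 1 of 24 higher, HMMR at 1.00 ± 0.21, and 0 lower (0 and 0 adjusted over the list alone). Their adjusted p was 0.0474, and adjusted p = 0.934 with an estimated correlation. The G2/M call ended with quantile normalization (0.35) or median centring (0.63), without either RNA sample of PC9M2 (0.60 and 0.55) and without PC9 replicates 1 and 3 (0.25), and the median was 0.84 without PC9 replicates 2 and 4. It also ended without any 1 of the arrays PC9M2 replicate 1 (0.50), PC9 replicate 3 (0.51) or PC9 replicate 4 (0.51). With only probes above background on all 16 arrays, TGF-beta targets (−0.65), ERBB receptors and ligands (−0.09), cyclin-dependent kinase inhibitors (−0.29) and G2/M genes (0.52) were not called. With normexp background correction the interferon median was −0.62 and the ERBB median −0.38, and the ERBB median was −1.0 without PC9 replicates 2 and 4.

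**Figure D3:**
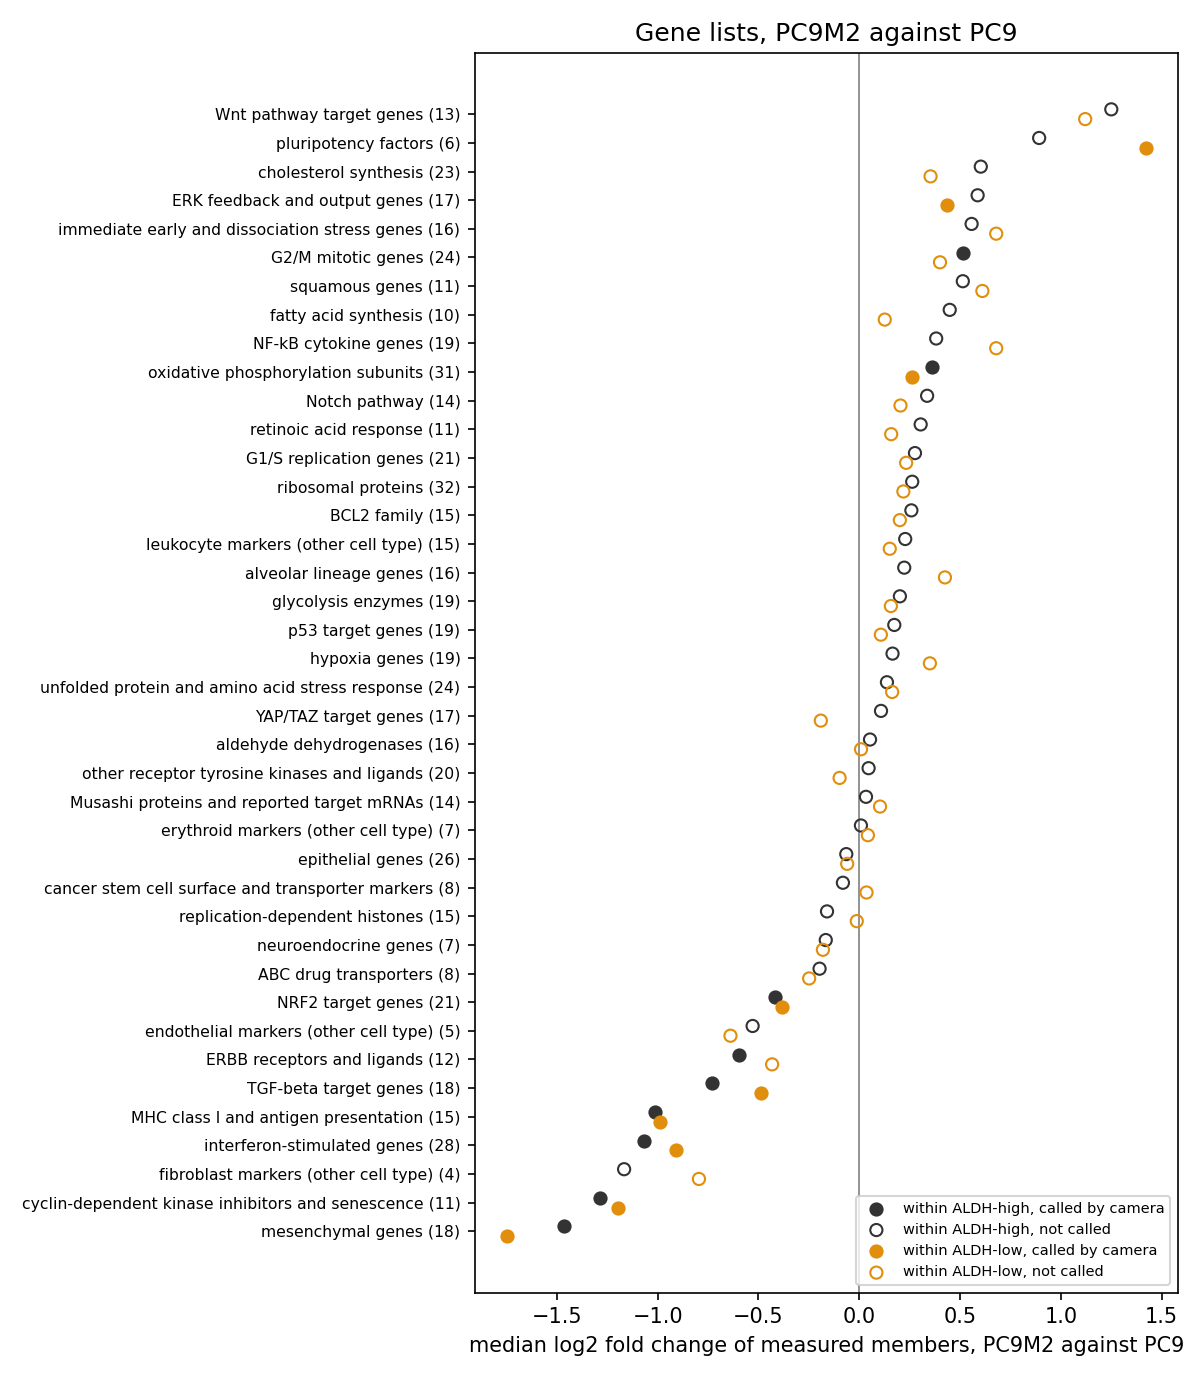
Median log2 fold change (horizontal axis) of the measured members of 40 gene lists (vertical axis) for PC9M2 against PC9, in black for ALDH-high and in orange for ALDH-low, with filled points for lists called by camera. Mesenchymal genes have medians of −1.46 and −1.75.

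Other lists were not called in this comparison, and counts adjusted over the list alone follow in brackets. ERK feedback genes, which follow MAPK output, had a median of 0.59 (adjusted p = 0.0562) with 4 of 17 higher (7), SPRY1 (2.00 ± 0.35), ETV5 (1.74 ± 0.34), SPRY4 (1.61 ± 0.30) and DUSP6 (1.56 ± 0.18). Among the 14 measured Musashi proteins and reported target mRNAs 4 rose and 1 fell (4 and 1), with a median of 0.03 (adjusted p = 0.743), and the members included MSI2, MYC (1.27 ± 0.20), SMAD3 (1.02 ± 0.19) and CDKN1A. Aldehyde dehydrogenases had 1 of 16 higher (1), ALDH16A1 (1.25 ± 0.21), a median of 0.05, and a mean of −0.15 with a downward test (adjusted p = 0.947). ALDH1A1 entered that list with the probe that stood for the gene and not with its second probe. Pluripotency factors had SALL4 (3.10 ± 0.34) and MYC higher and POU5F1 (−1.43 ± 0.34) lower among 6 (3 and 1), with a median of 0.89 (adjusted p = 0.221). Of 8 stem cell surface and transporter markers, CXCR4 was at least 30.6-fold lower and ALCAM (−2.15 ± 0.20) and ABCG2 (−1.79 ± 0.32) fell (3 lower and 1 higher), with a median of −0.08 (adjusted p = 0.206). Wnt targets had a median of 1.25 (adjusted p = 0.781), 3 of 13 higher and 1 lower (5 and 3), with LEF1 at 2.04 ± 0.49 and SP5 at −1.06 ± 0.18. Alveolar lineage genes had a median of 0.22 (adjusted p = 0.206) with 3 of 16 higher (4), among them FOXA1 (1.34 ± 0.17). Squamous genes had KRT15 (1.53 ± 0.34) higher and KRT17 (−4.50 ± 0.41) lower of 11 (1 and 1), a median of 0.51 and a mean of −0.31 with a downward test (adjusted p = 0.679). Epithelial genes had OCLN (1.32 ± 0.18), OVOL1 (0.90 ± 0.18) and ESRP2 (0.70 ± 0.17) higher of 26 (2), and a median of −0.06 (adjusted p = 0.983).

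Further lists with called members were Notch, with NRARP (1.74 ± 0.21) and NOTCH3 (1.17 ± 0.19) among 14 (median 0.34, adjusted p = 0.348). NF-kB cytokines had NFKBIA (1.59 ± 0.29) and TNFAIP2 (1.43 ± 0.25) higher of 19 (median 0.38, adjusted p = 0.308). YAP/TAZ targets had 3 of 17 lower, CCN2, TGFBI (−1.52 ± 0.19) and PTPN14 (−1.98 ± 0.22), with a median of 0.11 and a downward test (adjusted p = 0.366). ABC transporters had ABCC2 and ABCG2 lower of 8 (median −0.20, adjusted p = 0.374). The p53 targets had FDXR (1.19 ± 0.27) and BAX (1.11 ± 0.24) higher and CDKN1A and DDB2 (−1.43 ± 0.20) lower of 19 (median 0.17, adjusted p = 0.983). The BCL2 family had BAX higher and BIK (−1.56 ± 0.20) lower of 15 (median 0.26, adjusted p = 0.587). Other receptor tyrosine kinases and ligands had MET and AXL lower of 20, with a median of 0.05 and a downward test (adjusted p = 0.525). Stress response genes of unfolded protein and amino acid shortage had CEBPB (1.63 ± 0.24) and SEL1L (1.56 ± 0.19) higher and SLC7A11 lower of 24 (median 0.14, adjusted p = 0.705). Glycolysis enzymes had PFKL (0.89 ± 0.17) and PFKFB4 (0.74 ± 0.18) higher of 19 (median 0.20, adjusted p = 0.852), and cholesterol synthesis had NSDHL (1.14 ± 0.26) higher of 23 (median 0.60, adjusted p = 0.246). The 32 ribosomal proteins had a median of 0.26 (adjusted p = 0.117). In immediate early genes EGR3 was at least 2.23-fold higher, 1 of 16 (median 0.56, adjusted p = 0.246), and SYT1 (−1.47 ± 0.31) was lower among 7 neuroendocrine genes (median −0.17, adjusted p = 0.259). Of 5 endothelial markers PECAM1 (3.16 ± 0.40) was higher and EGFL7 (−0.81 ± 0.19) lower (median −0.53, mean 0.15, adjusted p = 0.715), and CD14 (−1.26 ± 0.19) was lower among 15 leukocyte markers (median 0.23, adjusted p = 0.983). No member was called among histones (median −0.16, adjusted p = 0.259), G1/S genes (0.28, adjusted p = 0.566) and fatty acid synthesis (0.45, adjusted p = 0.566). The same held for hypoxia genes (median 0.17, adjusted p = 0.982), retinoic acid response (0.30, adjusted p = 0.983) and erythroid markers (0.01, adjusted p = 0.983). With the replicate pair as a block, members of these lists were called. They were 0 higher and 2 lower for histones, 3 and 0 for G1/S genes and 4 and 1 for fatty acid synthesis. Hypoxia genes had 7 and 5, retinoic acid response 3 and 3, and erythroid markers 1 and 0.

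In total, 1084 of 17086 genes were higher and 1092 lower in ALDH-high PC9M2 (limma, Benjamini-Hochberg), and 799 and 983 of them changed by at least 2-fold. With the replicate pair as a block, 4517 were higher and 2894 lower, 3052 of them by at least 2-fold. All 2176 genes called without the block had the same sign in both replicate pairs and were also called with it. With arrays centred on their median, 1444 were higher and 981 lower, 59.5% higher against 49.8%. Of the 9 lists called, 0 were called with an estimated correlation, which held in all 5 comparisons. With the block and an estimated correlation, the smallest adjusted p of any list was 0.605 here. Each slide held all 4 groups, but each group lay in the same row of both slides, so line and row cannot be told apart. On the first slide alone 1960 genes were called, and on the second 2019. The slides held paired arrays that were taken as the same RNA samples from their agreement, so the likeness of the slides is no replication. A fit of the 16 arrays with slide as a fixed block and the replicate pair as a random block called 3431. Leaving out an RNA sample left 724 calls without PC9M2 replicates 1 and 3, 726 without PC9M2 replicates 2 and 4, 727 without PC9 replicates 1 and 3 and 815 without PC9 replicates 2 and 4.

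The second comparison set PC9M2 against PC9 among ALDH-low cells. MSI2 was higher in PC9M2 by 3.27 ± 0.65 (SE, n = 2 per group, adjusted p = 0.0265), with its dimmer probe at 0.12 ± 0.38. The MSI2 call ended without PC9M2 replicates 1 and 3 (2.68, adjusted p = 0.127), PC9M2 replicates 2 and 4 (3.87, adjusted p = 0.0526) or PC9 replicates 2 and 4 (2.57, adjusted p = 0.102). MET fell by 2.15 ± 0.18 (adjusted p = 0.0014) and AXL by 2.91 ± 0.32 (adjusted p = 0.00379). The lists of mesenchymal, antigen presentation and interferon-stimulated genes were lower, with medians of −1.75, −0.99 and −0.91 (each with adjusted p = 0.335 with an estimated correlation). The pluripotency list had a median of 1.42 with 3 of 6 members higher and 1 lower, and the ERK feedback list a median of 0.43 with 5 of 17 higher. These lists had adjusted p = 0.335 and 0.412 with an estimated correlation, and with the replicate block they were not called (adjusted p = 0.178 and 0.139). EGFR differed by −0.51 ± 0.59 (adjusted p = 0.652, and 0.0122 with the block), MSI1 by −0.30 ± 0.26 (adjusted p = 0.533) and ALDH1A3 by 0.30 ± 0.32 (adjusted p = 0.619). ALDH3A1 differed by −1.39 ± 0.66 (adjusted p = 0.251, and 0.0191 with the block) and ALDH1A1 by −0.52 ± 0.64 (adjusted p = 0.68). The second ALDH1A1 probe was again above background in PC9 only, at least 50.9-fold lower in PC9M2 (adjusted p = 0.0126 over all probes).

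Again among genes above background on every array of the groups compared, the largest rises were in S100A9 (8.29 ± 0.17), the oxidase subunit CYBA (7.89 ± 0.20), SLC1A3 (7.11 ± 0.27), DHRS2 (6.52 ± 0.29), the collagen COL13A1 (5.76 ± 0.31), PI3 (5.64 ± 0.80), HOXC13 (5.62 ± 0.36) and OLFML3 (5.59 ± 0.25). The largest falls were in CES1 (−7.77 ± 0.19), the cancer-testis gene SPANXA1 (−7.76 ± 0.32), NR0B1 (−7.55 ± 0.81), BAIAP2L2 (−7.42 ± 0.97), DOCK10 (−6.63 ± 0.45), CAVIN3 (−6.37 ± 0.35), CDH2 (−6.36 ± 0.29) and SPARC (−6.06 ± 0.37). By lower bound, the keratin KRT23 was at least 1672-fold higher (adjusted p = 7.49e-05), SLC1A6 at least 346-fold (adjusted p = 4.4e-05), TCF4 at least 267-fold (adjusted p = 7.55e-05) and MAGEA9 at least 240-fold (adjusted p = 1.33e-05). The phosphatase ACP5 was at least 554-fold lower (adjusted p = 7.49e-05), HTRA1 at least 303-fold (adjusted p = 2.45e-05), PTN at least 205-fold (adjusted p = 1.77e-05) and PTPRR at least 132-fold (adjusted p = 8.1e-05).

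Mesenchymal genes fell in 10 of 18 cases and rose in 0 (11 and 0 adjusted over the list alone). TWIST2 was at least 36.9-fold lower (list adjusted p = 2.03e-09, and adjusted p = 0.335 with an estimated correlation). MHC class I and antigen presentation genes fell in 8 of 15 cases (10 adjusted over the list alone), among them PSMB9 (−3.10 ± 0.42), TAP1 (−2.12 ± 0.23) and HLA-B (−1.63 ± 0.23). Their adjusted p was 1.88e-06, and adjusted p = 0.335 with an estimated correlation. Interferon-stimulated genes fell in 11 of 28 cases (13 lower and 1 higher adjusted over the list alone). XAF1 changed by −5.34 ± 0.52, HERC5 by −4.30 ± 0.54 and IFI44 by −4.17 ± 0.48, where XAF1 and IFI44 were above background on 1 of 4 PC9M2 arrays (list adjusted p = 3.59e-06, and adjusted p = 0.335 with an estimated correlation). TGF-beta targets had a median of −0.49, with 5 of 18 lower and 1 higher (8 and 1 adjusted over the list alone), CCN2 at −5.87 ± 0.81 (above background on 2 of 4 PC9M2 arrays) and TIMP3 at 1.47 ± 0.27. That list had adjusted p = 0.0272, and adjusted p = 0.335 with an estimated correlation. Its median was −0.34 without PC9 replicates 1 and 3, where the call ended, −0.76 without PC9M2 replicates 1 and 3 and −0.28 without PC9M2 replicates 2 and 4. Cyclin-dependent kinase inhibitors and senescence genes had a median of −1.20 with 2 of 11 lower (5 lower and 1 higher adjusted over the list alone). IGFBP7, above background on 3 of 4 PC9M2 arrays, changed by −10.27 ± 0.17 (list adjusted p = 0.0272, and adjusted p = 0.335 with an estimated correlation). The median of that list was −0.68 without PC9M2 replicates 2 and 4, −0.78 without PC9 replicates 1 and 3 and −0.63 with normexp background correction. With only probes above background on all 16 arrays, TGF-beta targets (−0.22), cyclin-dependent kinase inhibitors (−0.24) and pluripotency factors (1.12) were not called.

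Pluripotency factors had 3 of 6 higher and 1 lower (4 and 1 adjusted over the list alone), SOX2 at least 4.92-fold, SALL4 (3.46 ± 0.34), MYC (1.12 ± 0.20) and POU5F1 (−1.52 ± 0.34). Their adjusted p was 0.0448, adjusted p = 0.335 with an estimated correlation and 0.178 with the replicate block. The call ended with median centring (1.53), with no filter (0.55), without PC9M2 replicates 1 and 3 (1.43) and without PC9 replicates 1 and 3 (1.14). ERK feedback genes rose in 5 of 17 cases (6 adjusted over the list alone), among them DUSP6 (2.37 ± 0.18), SPRY1 (2.32 ± 0.35), ETV5 (1.83 ± 0.34) and SPRY4 (1.69 ± 0.30). Their adjusted p was 0.0413, adjusted p = 0.412 with an estimated correlation and 0.139 with the block. The call ended with quantile normalization (0.38), median centring (0.55), without PC9M2 replicates 1 and 3 (0.62) and without PC9 replicates 1 and 3 (0.39), and the median was 0.73 without PC9 replicates 2 and 4. Oxidative phosphorylation subunits had a median of 0.26 against 0.07 for all genes, and ATP5PB (1.24 ± 0.25) and ATP5F1A (1.09 ± 0.16) were higher of 31 (2 adjusted over the list alone). That list had adjusted p = 0.0368, and adjusted p = 0.724 with an estimated correlation. Their call ended with quantile normalization (0.13), without PC9M2 replicates 2 and 4 (0.21) and without PC9 replicates 1 and 3 (0.23). NRF2 targets had a median of −0.38 with SLC7A11 (−1.18 ± 0.28) and ABCC2 (−1.40 ± 0.26) lower of 21 (1 adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.801 with an estimated correlation). The NRF2 median was 0.09 without PC9 replicates 1 and 3, −0.30 without PC9M2 replicates 2 and 4, where the call ended as well, and −0.89 without PC9 replicates 2 and 4. ERBB receptors and ligands were not called (median −0.43, adjusted p = 0.0511) and went both ways, with NRG4 (−3.25 ± 0.40) and EGF (−2.60 ± 0.59) lower and EREG (3.19 ± 0.44) higher.

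Among ALDH-low cells 868 genes were higher and 1035 lower in PC9M2 (limma, adjusted over 17086 genes), and 683 and 938 changed by at least 2-fold. With the replicate block 3709 were higher and 2945 lower, 2852 of them by at least 2-fold, and with median centring 1169 were higher and 926 lower. The first slide alone gave 1726 calls and the second 1801, again from paired arrays taken as the same RNA samples. The 16 arrays with slide as a fixed block and the replicate pair as a random block gave 3017. Leaving out an RNA sample left 772 calls without PC9M2 replicates 1 and 3, 826 without PC9M2 replicates 2 and 4, 870 without PC9 replicates 1 and 3 and 950 without PC9 replicates 2 and 4. The line effects in ALDH-high and ALDH-low share no sample but were not independent. Same-numbered arrays of 1 line deviated together from their group means (r of 0.830 to 0.892). The line effects had a Pearson r of 0.964 and a Spearman rho of 0.921 across 17086 genes, which are not independent replicates. Of the called genes 774 were higher in both and 907 lower in both, and 0 were called in opposite directions. Independent lists would give 55.1 and 66.1, but these 2 lists are not independent.

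**Figure D4:**
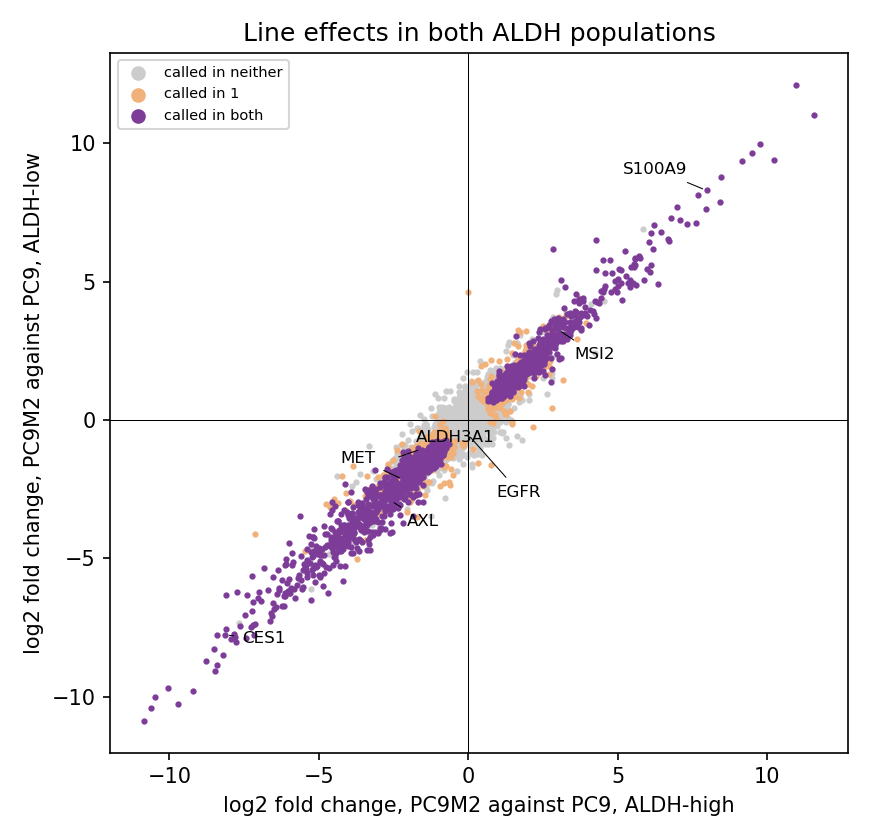
Log2 fold change of PC9M2 against PC9 in ALDH-high (horizontal axis) and ALDH-low (vertical axis) for 17086 genes, in which each point is 1 gene, grey where called in neither comparison, orange in 1 and purple in both. The points lie along the diagonal (r = 0.964), and 0 genes were called in opposite directions.

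The third comparison set ALDH-high against ALDH-low cells within PC9. The list of replication-dependent histones, made as DNA is copied, was higher in ALDH-high, with a median of 0.41 and 14 of 15 members above 0 (adjusted p = 0.764 with an estimated correlation). Its members included H1-2 (0.43 ± 0.30) and H4C3 (0.18 ± 0.20, SE, n = 2 per group). ERBB receptors and ligands (0.17), interferon-stimulated genes (0.18), NF-kB cytokines (0.18) and the 5 endothelial markers (0.21) were also higher, and fatty acid synthesis genes were lower (−0.24, with 0 of 10 above 0). These lists too had adjusted p = 0.764 with an estimated correlation, and ERBB (adjusted p = 0.0532) and endothelial markers (adjusted p = 0.0595) were not called with the replicate pair as a block. No single gene was called, and 0 members of these lists were called over all genes or adjusted over the list alone. The ALDH genes themselves differed by 0.95 ± 0.64 for ALDH1A1, 0.47 ± 0.32 for ALDH1A3 and 0.42 ± 0.66 for ALDH3A1. The second ALDH1A1 probe differed by 1.16 ± 1.00 and was not called either. ALDH1A3 was higher in both replicate pairs (0.44 and 0.51) and was not called with the block (adjusted p = 0.654). MSI2 differed by 0.15 ± 0.65, MSI1 by −0.07 ± 0.26, EGFR by −0.42 ± 0.59, MET by −0.11 ± 0.18 and AXL by −0.56 ± 0.32.

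The histone list had camera adjusted p = 1.07e-09, ERBB and interferon-stimulated genes 0.0095, NF-kB cytokines 0.0198, and fatty acid synthesis and endothelial markers 0.0492. Each of these lists had adjusted p = 0.764 with an estimated correlation. With the block and an estimated correlation, the smallest adjusted p of any list was 0.634. With the block and the preset correlation, cholesterol synthesis (−0.24, adjusted p = 0.00145), glycolysis enzymes (−0.19, adjusted p = 0.0249), oxidative phosphorylation subunits (−0.10, adjusted p = 0.0348) and G2/M genes (0.10, adjusted p = 0.0348) were called as well. Limma called 0 genes, with 181 at an unadjusted p under 0.05 against 854.3 expected by chance. This fit left the difference between the replicate pairs in the spread, so the low count does not show that the populations are alike. In simulated data the fit called 0.896% of genes changed by 1 on the log2 scale, and 64.6% with the replicate block. The simulated pair effect was shared by all groups, so these shares hold for that setting only. With the block limma called 0, with 1050 at an unadjusted p under 0.05, and with the arrays as 16 samples it called 50.

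These list medians moved with single RNA samples. Without PC9 ALDH-high replicates 2 and 4 the histone median was 0.19, that of NF-kB cytokines −0.04 and that of fatty acid synthesis 0.10, and none of the 6 lists was called. Without PC9 ALDH-low replicates 1 and 3 they were 0.14, 0.04 and 0.27 and were not called, while ERBB and interferon-stimulated genes stood at 0.39 and 0.36. Without PC9 ALDH-high replicates 1 and 3, ERBB (0.06) and interferon-stimulated genes (0.13) were not called, and NF-kB cytokines and fatty acid synthesis stood at 0.54 and −0.48. Without PC9 ALDH-low replicates 2 and 4, ERBB (0.09) and interferon-stimulated genes (0.05) were not called, and NF-kB cytokines and fatty acid synthesis stood at 0.29 and −0.63. Endothelial markers lost their call without any 1 of these 4 RNA samples (0.15 to 0.26), and without the ALDH-high array of replicate 1 (0.16) or 2 (0.22) or the ALDH-low array of replicate 2 (0.21) or 3 (0.21). Fatty acid synthesis was not called without the ALDH-high array of replicate 3 (−0.24) or the ALDH-low array of replicate 2 (−0.25) or 3 (−0.25).

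The fourth comparison set ALDH-high against ALDH-low cells within PC9M2. The G2/M mitotic list was higher in ALDH-high, with a median of 0.26 and 24 of 24 members above 0, among them BIRC5 (0.18 ± 0.40) and CENPF (0.13 ± 0.32, SE, n = 2 per group). It had adjusted p = 0.968 with an estimated correlation, as had the lists that follow. Replication-dependent histones were higher as well (0.26), with H1-2 at 0.23 ± 0.30, and so were MHC class I and antigen presentation genes (0.15, with 15 of 15 above 0), such as HLA-E (0.09 ± 0.17). Hypoxia genes were lower (−0.27), among them the glucose transporter SLC2A1 (−0.28 ± 0.38) and NDRG1 (−0.29 ± 0.37). None of these members was called over all genes or adjusted over the list alone. ALDH1A1 differed by 0.17 ± 0.64, ALDH1A3 by 0.47 ± 0.32, ALDH3A1 by −0.65 ± 0.66, MSI2 by −0.13 ± 0.65, MSI1 by −0.03 ± 0.26, EGFR by 0.07 ± 0.59, MET by −0.14 ± 0.18 and AXL by −0.25 ± 0.32. ALDH1A3 was at 0.53 and 0.40 in the replicate pairs (adjusted p = 0.815 with the block).

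The camera adjusted p was 0.000906 for G2/M genes, 0.00284 for hypoxia, 0.00413 for histones and 0.0055 for MHC class I. Each of them had adjusted p = 0.968 with an estimated correlation, and interferon-stimulated genes (0.17) were called with the replicate block only (adjusted p = 0.0483, and adjusted p = 0.969 with an estimated correlation as well). Limma called 0 genes, with 178 at an unadjusted p under 0.05. With the block it called 0, with 687 at an unadjusted p under 0.05, and with the arrays as 16 samples it called 32. Without PC9M2 ALDH-high replicates 1 and 3, MHC class I (0.03) and hypoxia (−0.09) were not called and histones stood at 0.52. Without PC9M2 ALDH-high replicates 2 and 4, G2/M genes (0.16) and histones (0.05) were not called, and MHC class I and hypoxia stood at 0.34 and −0.45. Without PC9M2 ALDH-low replicates 1 and 3, G2/M genes (0.03), histones (−0.04) and hypoxia (−0.37) were not called, MHC class I stood at 0.32, and limma called 1 gene. Without PC9M2 ALDH-low replicates 2 and 4, MHC class I (0.00) and hypoxia (−0.18) were not called, and G2/M genes and histones stood at 0.46 and 0.66. The ALDH effects of the lines had a Pearson r of 0.191 and a Spearman rho of 0.183 across 17086 genes, which are not independent replicates.

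The last comparison asked whether the line effect differed between ALDH-high and ALDH-low cells. YAP/TAZ target genes, which respond to cell contact and stiffness, had a line effect that was higher in ALDH-high. The median difference was 0.34 with 17 of 17 members above 0, among them AMOTL2 (0.34 ± 0.42) and CCN1 (0.18 ± 0.46, SE). Replication-dependent histones had a lower one, with a median of −0.19 and 1 of 15 above 0, H1-2 at −0.19 ± 0.42. Both lists had camera adjusted p = 0.0376, and adjusted p = 0.885 with an estimated correlation, with 0 members called over all genes or adjusted over the list alone. MSI2 differed by −0.28 ± 0.91, MSI1 by 0.04 ± 0.37, ALDH1A1 by −0.78 ± 0.91 and ALDH1A3 by −0.01 ± 0.45. ALDH3A1 differed by −1.07 ± 0.94, EGFR by 0.49 ± 0.83, MET by −0.03 ± 0.26 and AXL by 0.31 ± 0.45, and none of them was called. Limma called 0 genes, with 118 at an unadjusted p under 0.05, 0 with the block (574 at an unadjusted p under 0.05) and 9 with the arrays as 16 samples. The YAP/TAZ call ended without PC9M2 replicates 1 and 3 of ALDH-high (0.08), replicates 2 and 4 of ALDH-low (0.08), and any 1 RNA sample of PC9 (0.15 to 0.36). It also ended without the array of PC9M2 ALDH-high replicate 1 (0.33) or ALDH-low replicate 4 (0.33), and its median was 0.55 and 0.56 without either other RNA sample of PC9M2. The histone median was 0.04 without PC9M2 ALDH-high replicates 1 and 3, 0.18 without PC9M2 ALDH-low replicates 2 and 4, 0.02 without PC9 ALDH-high replicates 2 and 4 and 0.11 without PC9 ALDH-low replicates 1 and 3. It lay between −0.36 and −0.48 without each of the other 4 RNA samples. Its call also ended without the array of PC9M2 ALDH-high replicate 1, PC9M2 ALDH-low replicate 1, 2 or 4, PC9 ALDH-high replicate 1 or PC9 ALDH-low replicate 4, each at −0.18 or −0.19.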

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

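The camera tests of lists on the difference of the line effects were planned. The other tests in this part were chosen after the results they measure were seen, except that of the spike-in controls and that of a gradient along the slides, which were chosen before. Probes without a gene name, which no comparison of the report used, also differed between the lines. In ALDH-high cells 766 of 11547 such probes were called by limma (337 higher and 429 lower in PC9M2, 2492 at an unadjusted p under 0.05), and in ALDH-low cells 697 (266 higher and 431 lower, 2297 at an unadjusted p under 0.05). The line effect differed between ALDH-high and ALDH-low for YAP/TAZ target genes (median difference 0.34, 17 of 17 members above 0, camera adjusted p = 0.0376) and, the other way, for replication-dependent histones (−0.19, 1 of 15 above 0, adjusted p = 0.0376), and both had adjusted p = 0.885 with an estimated correlation.

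Replicates 2 and 4 differed from replicates 1 and 3 in all 4 groups, only partly alike in the 2 lines (r of 0.574 to 0.665 between lines and 0.830 to 0.892 within a line), and limma with the pair as a factor called 7394 genes (4530 higher and 2864 lower). Synthetic RNAs added in equal amounts argue against labelling or hybridisation for the differences from gene to gene, as far as 7 bright probes can show it. These scattered by a median robust SD of 0.0318 between the pairs, each as the median of about 35 spots, which hides local position effects. Replicates 1 and 3 lay in the first column of both slides and replicates 2 and 4 in the second, so pair and slide column cannot be told apart. The 7 probes did shift together, by −0.94 to −0.18 in the 4 groups, so a part from RNA input or labelling common to all genes was not excluded. A common shift in signal would leave no more scatter than between arrays of 1 pair (at most 0.116), but gene probes scattered by a robust SD of at least 0.403 between arrays of different pairs. A difference between the RNA samples themselves, for example between cultures or days, is consistent with both scatters, but the labels name no such batch and no biological explanation was tested.

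The ALDH effect had a small part shared by both lines and both replicate pairs, with 51 genes beyond 0.5 in 1 direction in all 4 comparisons (39 higher and 12 lower, 33 protein coding, 23 above background on all 16 arrays), against at most 8 genes for any of the other sign patterns. Among the 23, with examples picked after the values were seen, HSPA6, a heat shock protein, was higher in ALDH-high by 2.39 ± 0.19 (SE with the replicate block), SAA1, an acute phase protein, by 1.03 ± 0.17 and CYP4B1 by 0.81 ± 0.10, while the small nucleolar RNA SNORD4B changed by −1.16 ± 0.16. An even gradient along the rows of the slides would give these genes a line effect about double their ALDH effect. The median ratio was −0.461, with quartiles of −0.969 and 0.702. The line effect also holds any line difference of these genes, so the ratio does not exclude a gradient. ALDH-high lay in rows 1 and 3 and ALDH-low in rows 2 and 4 of both slides, so an effect of single rows cannot be told apart from ALDH. A change common to ALDH-high cells of both lines may account for the pattern, and an effect of separating the populations was not tested, because the labels do not state how it was done. No gene was called for the ALDH effect averaged over the lines (limma, 0 with the block, smallest adjusted p 0.164, 1056 at an unadjusted p under 0.05, and 0 without the block, 235 at an unadjusted p under 0.05).

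In the authors' processed values 12 of 16 columns held another array than their sample name, and as labelled they called 0 genes between the lines in ALDH-high cells but 8251 between ALDH-high and ALDH-low in PC9. All 16 columns followed an exchange of group order and replicate number, which suggests that they were written in another order than their labels. The opposite explanation, wrong labels on the scanner files, was first tested by the ratio of distances within groups to those between groups, which was 0.991 with the column labels and 0.542 with the scanner labels and did not reach the bound of 1 set for it. A second test was then chosen, in which the 8 pairs of arrays that agree within spot noise (highest ratio 1.03) were all put in different lines by the column labels. The second test argues against the column labels being right. It cannot show whether whole groups were exchanged among the scanner files, because the pairs would stay together. No record of the samples outside the files was available.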

How the results depend on the processing

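The 16-array fit without a block had been planned as the main fit, and the replicate pairs in the block fits were set from the data. The 16-array fit with a replicate block, the fits without an RNA sample, the fits on 1 slide, the matched columns and the fit of all probes were chosen after the data were seen. The values for single genes and lists were counted under all alternatives except the authors' columns as labelled. Of these, 6228 kept their direction and their side of the threshold, 621 lost their call, 19 gained one and 53 changed sign. With the authors' columns as labelled, which hold other arrays, 94 of 215 values changed sign. Of the counts and correlations, 404 stayed within 1.5 times or 0.1 of the value reported and 106 did not. Where no cause is given, the cause was not tested. A gene above background in 1 group only is given as a lower bound, and a fitted value of a gene above background on some arrays of a group is less certain. Other splits of the samples were not counted with n = 2, and the fit on only the groups compared was not run for the difference of effects.

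With an estimated correlation 0 lists were called in each of the 5 comparisons. Median centring turned EGFR in ALDH-high cells to 0.0899. Normexp called 12 lists for ALDH in PC9 and 4 for the difference and turned ALDH1A3 in the difference to 0.0279. The authors' columns as labelled, which hold other arrays, called 0 genes (0 at 2-fold) and 2 lists for the lines in ALDH-high, and 1 gene (1) and 0 lists in ALDH-low. They called 8251 genes (1040) and 10 lists for ALDH in PC9, 8417 genes (1103) and 11 lists in PC9M2, and 0 lists for the difference, with correlations of 0.391 between line effects and 0.940 between ALDH effects. With probes above background on all 16 arrays, so fewer genes, the lines differed in 1141 genes at 2-fold in ALDH-high and in 1266 (1019) in ALDH-low, and 13 lists were called for ALDH in PC9. The mean of a gene's probes gave 10 lists for ALDH in PC9, 5 for the difference and MSI2 at −0.0267 for ALDH in PC9. With only the groups compared, so fewer samples, the lines differed in 1242 genes in ALDH-high and 800 (800) in ALDH-low.

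With the replicate block, which fits the paired samples, the lines differed in 7411 genes (3052 at 2-fold) in ALDH-high and 6654 (2852) in ALDH-low. The block ended the calls of pluripotency factors (adjusted p = 0.178) and ERK feedback genes (0.139) in ALDH-low and of ERBB (0.0532) and endothelial markers (0.0595) for ALDH in PC9. It added the lists and the named genes ALDH1A1, ALDH3A1 and EGFR given beside their values, and changed no other call of a named gene or list. With the arrays as 16 samples, which count each averaged RNA sample 2 times, the counts were 7698 (3010), 7081 (2835), 50 (11), 32 (17) and 9 (7) in the order of the report, with 4 lists for the difference. With the replicate block as well they were 11421 (3212), 10929 (3044), 1583 (60), 420 (55) and 404 (53). The 16 arrays with slide as a fixed block and the replicate pair as a random block gave 3431 and 3017 genes between the lines, with 4 lists for the difference, and slide and the use of 16 arrays were not told apart. All probes gave 3558 and 3184. The first slide alone gave 1 gene (1) for ALDH in PC9M2, 1 (1) for the difference and MSI1 at −0.10 in the difference, and the second gave 2 lists for ALDH in PC9, 1 for the difference and MSI1 at 0.14 for ALDH in PC9M2.

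Leaving out 1 array or RNA sample, which leaves a group with fewer samples and assumes that a lone sample varies like the others, gave these ranges. The lines in ALDH-high had 724 to 2186 genes (724 to 1787 at 2-fold), 8 to 12 lists, MSI1 −0.60 to 0.0679 and EGFR −0.53 to 0.48. The lines in ALDH-low had 772 to 1910 genes (772 to 1633), 6 to 13 lists, NRF2 targets −0.89 to 0.0890, ALDH1A1 −1.30 to 0.26 and EGFR −1.04 to 0.0122. ALDH in PC9 had 0 to 0 genes, 1 to 10 lists, NF-kB cytokines −0.0361 to 0.54, fatty acid synthesis −0.63 to 0.27, MSI2 −0.54 to 0.85, MSI1 −0.15 to 0.0155 and ALDH3A1 −0.33 to 1.17. ALDH in PC9M2 had 0 to 1 gene (0 to 1), 4 to 7 lists, histones −0.0427 to 0.66, MSI2 −0.72 to 0.47, MSI1 −0.37 to 0.30 and ALDH1A1 −0.0629 to 0.41. The difference had 0 to 1 gene (0 to 1), 0 to 9 lists, histones −0.48 to 0.18, MSI2 −0.98 to 0.42, MSI1 −0.30 to 0.37, ALDH1A1 −1.56 to 0.00168 and ALDH1A3 −0.29 to 0.27.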

Other observations

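The tests of gene families in this part were chosen after the largest changes had been seen, as was the comparison of the replicate pairs. The filter kept genes above background in any 1 group. Family members seen in 1 line only, such as MAGEA9 and MAGEA10, could thus enter the family tests through that line. Fisher's exact test, used for the families, also takes members as independent. Its p-values are therefore descriptive and no measure of enrichment. Cancer-testis antigen genes, normally expressed in the germline, differed between the lines in both directions. In ALDH-high cells 8 of 32 tested members were higher in PC9M2 and 12 lower, 62.5% against 12.6% of other genes (Fisher's exact test, two-sided, adjusted over 13 families, p = 7.38e-10, odds ratio 11.5), and in ALDH-low cells as many were (adjusted p = 6.12e-11). SPANXB1 (−10.85 ± 0.50, SE, n = 2 per group), SPANXC (−10.60 ± 0.35) and CTAG1A (−4.51 ± 0.45) fell, with signals above background on 2, 2 and 1 of the 4 PC9M2 arrays, and MAGEA10 was at least 24.1-fold lower. MAGEA8 (4.74 ± 0.76, above background on 1 of 4 PC9 arrays), MAGEA4 (2.71 ± 0.20) and MAGEA1 (2.50 ± 0.18) rose. MHC class II genes, which present antigen to helper T cells, fell in 9 of 13 cases in ALDH-high cells (adjusted p = 2.49e-05) and in 8 in ALDH-low cells (adjusted p = 7.77e-05), among them HLA-DMB (−4.88 ± 0.70, above background on 2 of 4 PC9M2 arrays) and HLA-DQB1 (−2.05 ± 0.20). Collagens went both ways, with 3 of 30 higher and 10 lower in ALDH-high cells (adjusted p = 0.000141) and 3 and 11 in ALDH-low cells (adjusted p = 7.21e-06). COL4A4 (−5.21 ± 0.56), COL4A6 (−5.20 ± 0.37) and COL5A1 (−4.06 ± 0.39) fell, and COL13A1 (4.49 ± 0.31), COL6A1 (2.74 ± 0.62) and COL6A2 (2.64 ± 0.34) rose. Of 16 S100 genes 3 rose and 3 fell (adjusted p = 0.0354), with S100A8 at 11.56 ± 0.36, S100A12 at 5.0 ± 0.16 and S100A4 at −2.80 ± 0.32. S100A8 and S100A12 were above background on 2 of 4 PC9 arrays each. Protocadherins had a Fisher adjusted p of 0.505 in ALDH-high and 0.0481 in ALDH-low cells. Of 439 zinc finger genes 57 were higher and 11 lower in ALDH-high cells (Fisher adjusted p = 0.177). Fisher's test set called against uncalled genes, so the direction of change was not tested for any family.

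Of 40 lists 15 were called between the replicate pairs, 5 higher and 10 lower in replicates 2 and 4, and 0 with an estimated correlation (smallest adjusted p 0.821). In replicates 2 and 4, squamous genes were higher by a median of 2.36 (9 of 11 called, camera adjusted p = 0.00814, and adjusted p = 0.821 with an estimated correlation), among them KRT6B (3.66 ± 0.72) and KRT5 (2.36 ± 0.17). The same held for G1/S genes (0.75, 15 of 21, adjusted p = 0.00111), G2/M genes (0.57, 16 of 24, adjusted p = 0.00292) and histones (0.42, 10 of 15, adjusted p = 0.00563), with adjusted p = 0.852, 0.852 and 0.837 with an estimated correlation. Cholesterol synthesis genes were lower (−0.63, 16 of 23, adjusted p = 5.69e-08), and so were aldehyde dehydrogenases (−0.56, 10 of 16 lower and 1 higher, adjusted p = 0.00111) and retinoic acid response genes (−0.80, 6 of 11 lower and 2 higher, adjusted p = 0.0387), each with adjusted p = 0.821 with an estimated correlation. NUPR1 (−3.33 ± 0.12) and GDF15 (−2.89 ± 0.30), genes of the stress response, were lower, and CDH16 (4.36 ± 0.16) was higher.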
